A study of Mus musculus with 18 samples.

How the data were processed

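The authors deposited 1 table per group, 10 in all, with 1 count per Ensembl gene, and the count values were made by the authors before deposit. Per the submitters' processing notes reads were mapped to mm9. The aligner, the counting program, the removal of PCR copies, any filter on sites, and how the libraries of a group were joined are not given in the sources used here. The values are whole numbers, so they were treated as counts, and 0 columns of values were left unused. The tables cover 22933 genes (22463 protein coding, 470 lincRNA), with a median span of 14920 bp. Of these, 8643 had 0 counts in every table, and 1475 overlap another gene on the same strand. Whether counting was by strand is not stated, and exons and introns cannot be told apart. Symbols are those of the tables, and a later gene table gave a current symbol for 20273 genes (88.4%).

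Low counts showed signs of steps before deposit. In the Suz12 Ezh2 fl/fl table fewer genes had 1 count (197) than 2 (363) or 3 (444). Even numbers made up 70.4% of counts from 2 to 9 in Jarid2 WT, against 50.5% to 52.0% in the other deep tables. Among the shallow tables they made up 73.0% in Suz12 KO, 63.5% in IgG and 61.4% in Eed. There the number of genes fell steeply from 2 counts upward (374, 138, 42 and 15 genes at 2, 3, 4 and 5 in Suz12 KO). Such a fall alone makes even numbers the majority. In Jarid2 WT the numbers alternated instead (1071, 381, 865 and 276). For each deep table the expected count of a gene was its lowest share in the other deep tables times the table's total, so genes at or near 0 in any other table were left out. Of genes with at least 20 expected counts, those listed at 0 numbered 91 of 3180 for hnRNP C, 42 of 1805 for Jarid2 KO, 15 of 4323 for Fus, 2 of 3283 for Ezh2 d/d, 1 of 3297 for Jarid2 WT and 0 of 4316 for Ezh2 fl/fl. Against Ezh2 fl/fl alone more were listed at 0: 73 of the lower genes in Ezh2 d/d, 68 in Jarid2 WT and 1058 in Jarid2 KO.

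Since each group had 1 value per gene, no test between groups was made. A gene's share is its count over all counts in genes of the table, and 2 shares were compared as a ratio with an exact conditional binomial 95% interval. A gene was called different when it had at least 50 counts over both tables, a ratio of at least 2 in either direction and an interval excluding 1. How many genes counting error alone would call was found from 100 redraws of both tables from their pooled composition. For a gene list, the median log2 ratio (0.5 added to each count) was placed among 10000 random lists matched in 20 bins of mean count (seed 1), and percentiles below 2.5 or above 97.5 were called. The 15 lists were PRC2 subunits, Polycomb-repressed developmental regulators, pluripotency genes, primitive endoderm markers, fibroblast (feeder) markers, 2-cell-like markers, imprinted genes, long neuronal genes, long noncoding RNAs, small structured noncoding RNAs, mitochondrial-encoded genes, ribosomal protein genes, replication-dependent histone genes, splicing factor and hnRNP genes, and housekeeping mRNAs. The comparisons, thresholds and alternatives were chosen before the data were examined, apart from those named as later choices.

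Genes named are the 8 per direction whose interval bound nearest 1 lies farthest from it, the highest-count members of a list described, the targeted genes Ezh2, Suz12, Jarid2 and Eed, and the 10 highest of Suz12 in Ezh2 fl/fl and of the pooled controls. Other list members that passed 2-fold, and further genes with counts in both tables such as Wwox, were named after their values were seen. Gphn, Lars2 and Hexb were set down for a test before their values were seen. A self-test put known differences into redrawn counts: of 3-fold differences 99.0% were recovered for Ezh2 d/d, 93.8% for Jarid2 KO over WT, 98% for hnRNP C and 10% for Eed, and intervals covered the true ratio for 95.6% to 99.0% of genes. The redraws follow the counting model that the intervals assume, so this coverage checks the calculation and not whether the deposited counts follow that model.

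Alternatives were scaling by TMM and by median-of-ratios size factors, leaving out the 20 genes with the highest counts, other minimum counts and fold thresholds, thinning the deeper table, and leaving out overlapping genes. The tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0, the last 2 for scaling factors only.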

Results

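RNA bound by Suz12 was measured in mouse embryonic stem cells by iCLIP, in which ultraviolet light crosslinks protein to RNA before immunoprecipitation and the recovered RNA is sequenced. Suz12 is a core subunit of Polycomb repressive complex 2 (PRC2), the complex that methylates histone H3 at repressed developmental genes. The 18 libraries fell into 10 groups. Suz12 was precipitated from Ezh2 fl/fl cells (6 libraries) and from Ezh2 d/d cells (3 libraries), in which 800 nM 4-hydroxytamoxifen for 96 h deletes Ezh2, the catalytic subunit. Suz12 was also precipitated from Jarid2 wild-type (WT), Jarid2 knockout (KO) and Suz12 KO cells, with 1, 1 and 2 libraries. Jarid2 is a PRC2 cofactor. The other groups, with 1 library each, were Eed, a further PRC2 core subunit precipitated through a Myc tag from a separate conditional Eed line, the RNA-binding proteins Fus and hnRNP C, and the controls IgG and GFP. The labels tag Ezh2 d/d, Jarid2 WT and Suz12 KO cells as given tamoxifen and the other groups as not. The UV dose was 0.2 J/cm2 for libraries 5 and 6 of Ezh2 fl/fl, library 2 of Suz12 KO and GFP, and 0.15 J/cm2 for all others.

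Counts in genes totalled 3439875 for Suz12 in Ezh2 fl/fl, 1453577 in Ezh2 d/d, 1400120 in Jarid2 WT and 342574 in Jarid2 KO cells. Fus gave 3098339 counts and hnRNP C gave 1039998. The shallow groups were Eed with 6151 counts, IgG with 3287 and Suz12 in Suz12 KO cells with 1712. The GFP table held only zeros and its description names Suz12 in Jarid2 KO cells, so whether this library was counted is unclear. The libraries of a group were pooled into 1 value per gene, so no difference has a replicate check. Ratios compare each gene's share of all counts in genes, and their exact binomial 95% intervals cover counting error only, since counted reads need not be independent molecules.

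Suz12 recovered far more RNA from cells with Suz12 than from cells without it. Averaged over the pooled libraries, Suz12 in Ezh2 fl/fl cells gave 573312 counts per library and Suz12 in Suz12 KO cells gave 856, a ratio of 669.8 (95% interval 639 to 703). The ratio to IgG was 174 (169 to 181). Suz12 yields over Suz12 KO were 566 (539.8 to 594) in Ezh2 d/d, 1636 (1560 to 1716) in Jarid2 WT and 400.2 (382 to 419.9) in Jarid2 KO cells. Eed gave 7.19 times (6.81 to 7.59) the Suz12 KO yield and 1.87 times (1.79 to 1.95) the IgG yield. Fus and hnRNP C, precipitated from fewer cells than Suz12, gave 943 (911 to 976) and 316 (306 to 328) times the IgG yield. Yield also depends on how deeply each library was sequenced.

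**Figure D1:**
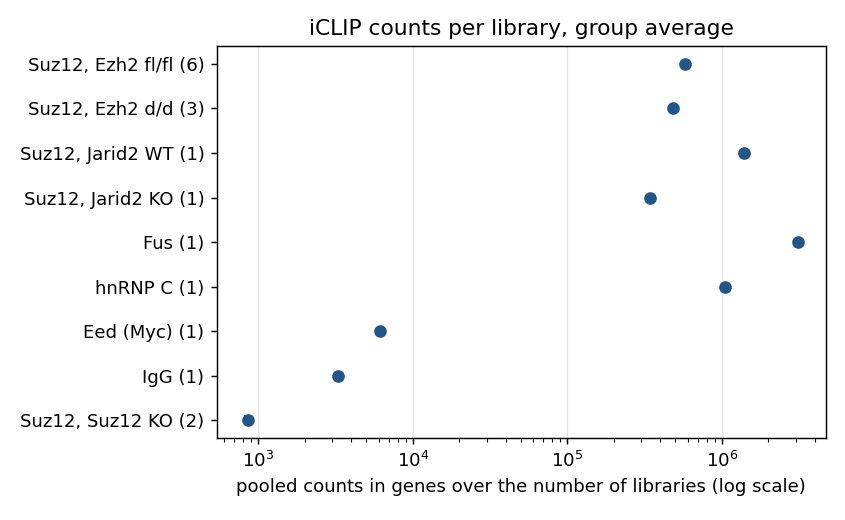
Pooled counts in genes divided by the number of libraries for each group (log scale), with the number of libraries in parentheses and exact Poisson 95% intervals that are mostly narrower than the points. Suz12 groups other than Suz12 KO average 342574 or more, Suz12 KO averages 856 and IgG has 3287; GFP, whose table holds only zeros, is not drawn.

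The genes with the most Suz12 counts in Ezh2 fl/fl cells were mostly long genes. Fgfr2, a fibroblast growth factor receptor (ENSMUSG00000030849, chromosome 7, 137305965 to 140315033 in mm9), led with 19752 counts. Etl4 (ENSMUSG00000036617, chromosome 2, 19831407 to 20732340) had 19411, and Msi2, an RNA-binding protein gene (ENSMUSG00000069769, chromosome 11, 88152884 to 88579827), had 17222. Ctbp2, a transcriptional corepressor gene (17019 counts), Galnt2 (14986), Arl15 (13067), Exoc4 (10736), Tead1 (10540), Macf1 (10202) and Ptprg (9706) completed the top 10. The counts of Fgfr2, Ctbp2 and Galnt2 are uncertain, since the listed Fgfr2 span overlaps 17 other genes on its strand, Ctbp2 lies almost wholly inside it, and the Galnt2 span overlaps 46 genes. In the pooled controls the highest counts were 31 for Eftud1, 24 each for Slc2a3, a glucose transporter gene, and Fgfr2, and 22 each for Msi2 and the splicing factor gene Sfpq. Ccdc44 (21), Galnt2 (18), Npm1, Macf1 and the E-cadherin gene Cdh1 (17 each) followed. Across genes, which are not independent replicates, Spearman correlations of shares with Ezh2 fl/fl were 0.842 for Ezh2 d/d, 0.857 for Jarid2 WT, 0.837 for Fus, 0.743 for hnRNP C and 0.725 for Jarid2 KO. For IgG and Suz12 KO they were 0.261 and 0.164, where thinning the fl/fl counts to those depths gave 0.515 and 0.414.

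The genes of the deleted proteins were checked in every group. Ezh2 (ENSMUSG00000029687, chromosome 6, 47480273 to 47545340) had 873 counts in Ezh2 d/d and 1672 in Ezh2 fl/fl, or 601 and 486 CPM. Jarid2 (ENSMUSG00000038518, chromosome 13, 44826640 to 45017006) had 1421 counts in Jarid2 KO and 6365 in Jarid2 WT, or 4148 and 4546 CPM. Suz12 (ENSMUSG00000017548, chromosome 11, 79806608 to 79847625) had 0 counts in Suz12 KO, against 2220 in Ezh2 fl/fl (645 CPM), where the upper 95% limit for 0 counts of 1712 is 2152 CPM. Gene-wide counts of a partly deleted gene do not check the deletion, because transcripts of the remaining part may still be counted, which was not tested.

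Primitive endoderm markers had higher shares of Suz12 counts in Ezh2 d/d than in Ezh2 fl/fl cells. Primitive endoderm is the extraembryonic lineage that makes basement membrane. Of 12 measured markers, 9 were at least 2-fold higher in Ezh2 d/d than in Ezh2 fl/fl and 0 were 2-fold lower. All 22 markers of the list together took 0.810% of counts in d/d and 0.327% in fl/fl, a ratio of 2.48 (2.41 to 2.54). Col4a1, a collagen of basement membrane, was 3.40-fold higher (3.18 to 3.64), Sparc 3.03-fold (2.82 to 3.25) and Lamb1-1, a laminin chain, 2.63-fold (2.43 to 2.84), while Lama1 was 1.90-fold higher (1.81 to 1.99). The list median was 1.37 on the log2 scale, at percentile 100 among 10000 random lists matched on mean count, which describes these libraries. The share was 0.483% in Fus from Ezh2 fl/fl cells and 0.129% in hnRNP C, with 1 count in IgG.

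Polycomb-repressed developmental regulators were barely covered: 5 of 104 had enough counts. Of these, 4 were higher in d/d, the transcription factor genes Gata4 (2.09-fold, 1.75 to 2.502), Gata6 (3.71, 2.51 to 5.55), Six1 (2.85, 1.83 to 4.48) and Lhx2 (3.47, 2.13 to 5.72). Gata4 and Gata6 are on the primitive endoderm list too. The median was 1.51, at percentile 99.8. Of 3 measured fibroblast markers, Col1a1 was 4.41-fold higher (2.76 to 7.18) and Timp3 4.48-fold (2.505 to 8.28), while Fn1 had a ratio of 1.03 (0.972 to 1.10). Their median was 2.13, at percentile 99.92, and the summed ratio of the whole list was 1.09 (1.03 to 1.16).

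Single genes with the clearest higher share in Ezh2 d/d included Krt18, a keratin of simple epithelia (ENSMUSG00000023043, chromosome 15, 101858659 to 101862451), with 58 counts against 2 in fl/fl (68.6-fold, 18.2 to 580.1). Plxdc2 (ENSMUSG00000026748, chromosome 2, 16277931 to 16677466) had 232 against 35 (15.7-fold, 10.96 to 23.1), and Clu, encoding the chaperone clusterin, was 11.6-fold higher (8.00 to 17.1). Emp2, Ano3, Nfia, Dnalc1 and Lhfp had ratios from 12.1 to 20.7, where the Nfia span overlaps another gene. Among lower genes, 7 were listed at 0 in d/d: BC046404 against 238 counts in fl/fl, B4galnt4 against 228, the sodium channel gene Scn8a against 211, Cnksr3 against 210, Xylt1 against 199, Taf8 against 198 and Prodh against 179. Bahcc1 (ENSMUSG00000039741, chromosome 11, 120094261 to 120153596) had 11 against 879, 33.8-fold lower (18.8 to 67.9).

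Splicing factor and hnRNP genes had slightly higher shares in Ezh2 d/d, with a summed ratio of 1.34 (1.33 to 1.35), a median of 0.44 and percentile 99.8, though 0 of 55 passed 2-fold. Sfpq was 1.65-fold higher (1.59 to 1.71) and Srrm2 had a ratio of 0.858 (0.817 to 0.902). Ribosomal protein genes had a median of 0.32, at percentile 99.8, with 4 of 69 at least 2-fold higher, including Rpl7 (2.61-fold), and 1 lower, Rpl36. Pluripotency genes had a median of -0.21, at percentile 4.69, and 29 of 33 were within 2-fold. Esrrb, an estrogen-related receptor of the pluripotency network, was 1.60-fold lower (1.51 to 1.70), Gdf3 was lower with a ratio of 0.101, and Klf5, Tbx3 and Lefty2 were 2.18-, 2.15- and 3.16-fold higher. Of 10 imprinted genes, the growth factor gene Igf2 was 5.19-fold higher (4.56 to 5.91), and Trappc9 and Snrpn were lower. Histone genes (1 of 26 higher, 4 lower), housekeeping mRNAs (3 of 29 higher, 3 lower) and long neuronal genes (1 of 12 higher, 3 lower) had medians inside the middle 95% of random lists. Among PRC2 subunits, Lcor was 2.18-fold higher and 11 of 12 were within 2-fold, with Suz12 at 1.58 (1.48 to 1.69), Ezh2 at 1.24 (1.14 to 1.34), Jarid2 at 0.967 (0.932 to 1.00) and Eed at 0.910 (0.783 to 1.05). The 1 measured 2-cell-like marker, Eif1a, had a ratio of 1.67 (1.44 to 1.94). Of 47 long noncoding RNAs only 2 were in the annotation, and AC150277.2 was 2.30-fold lower (1.64 to 3.29). None of the 42 small structured RNAs or 15 mitochondrial-encoded genes was in the annotation.

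Over all genes with at least 50 counts in both groups together, 2194 of 7263 differed at least 2-fold in Ezh2 d/d with an interval excluding 1, where redraws from the pooled composition gave a median of 20. Of these, 698 were higher and 1496 lower, 73 of the latter listed at 0. Genes that differ between separately made Suz12 libraries were about as many: Jarid2 WT and Ezh2 fl/fl, both with unmodified PRC2 but of different lines and tamoxifen tags, differed at 2140 of 7317 genes. Jarid2 WT counts from 2 to 9 were mostly even (70.4%), so their counting error may be understated. The tamoxifen treatment and the library preparation went with the genotype, and the pooled fl/fl counts mix UV doses while those of d/d do not.

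**Figure D2:**
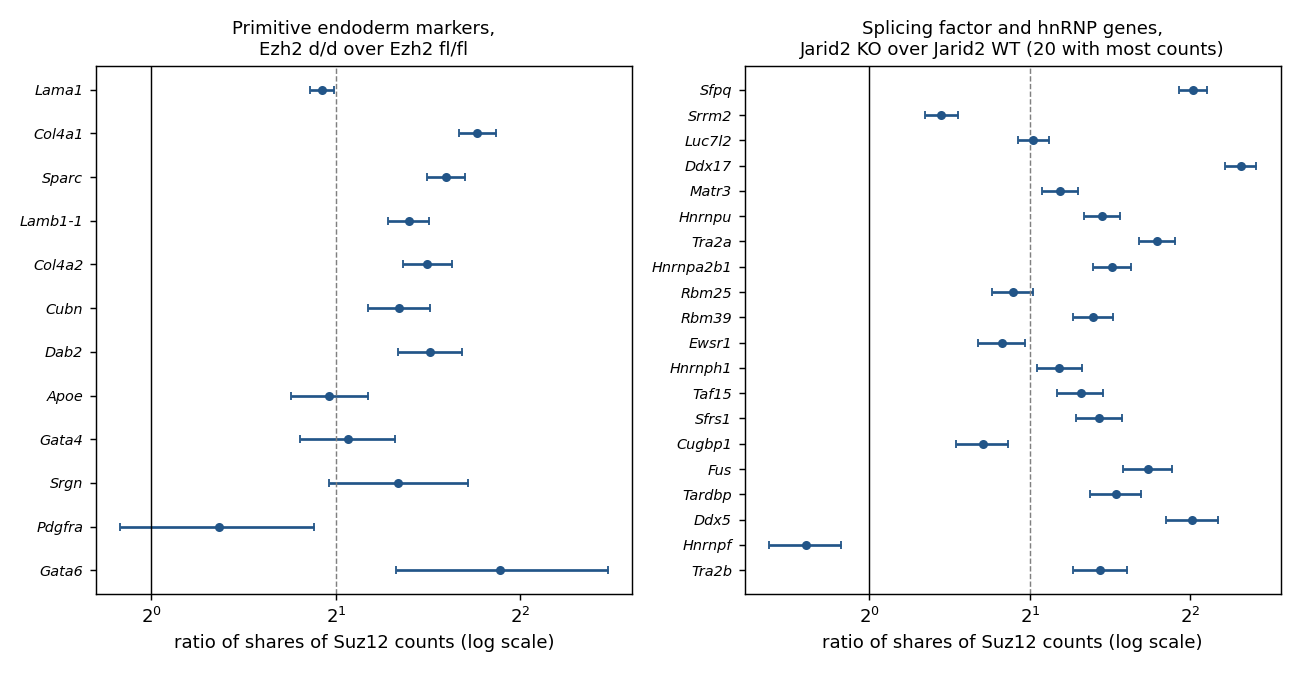
Ratios of shares of Suz12 counts (log scale, points) with exact 95% intervals (bars) for primitive endoderm markers, Ezh2 d/d over fl/fl (left), and for the 20 splicing factor and hnRNP genes with the most counts, Jarid2 KO over Jarid2 WT (right). Solid lines mark equal shares and dashed lines 2-fold; 9 of 12 markers pass 2-fold on the left, and Sfpq reaches 4.05 on the right.

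Splicing factor and hnRNP genes had higher shares of Suz12 counts in Jarid2 KO than in Jarid2 WT cells. Of 54 measured, 33 were at least 2-fold higher and 0 lower, and the list took 7.31% against 2.93% of counts, a ratio of 2.496 (2.46 to 2.54). Ddx17, an RNA helicase gene, was 4.98-fold higher (4.66 to 5.32), Sfpq 4.05-fold (3.81 to 4.30) and Luc7l2 2.03-fold (1.90 to 2.17), while Srrm2 had a ratio of 1.36 (1.27 to 1.46). The median was 1.35, at percentile 100. Against Ezh2 fl/fl, 34 of 55 were higher and 0 lower, with a summed ratio of 2.48 (2.44 to 2.51). The shallow files had shares of 4.44% for IgG (3.76 to 5.203), 4.88% for Eed (4.35 to 5.45) and 0.993% for Suz12 KO (0.579 to 1.59).

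Replication-dependent histone genes were also higher in Jarid2 KO cells, 7 of 8 measured, with a summed ratio of 2.66 (2.40 to 2.95) and a median of 1.26 at percentile 99.96. Hist1h4d was 4.42-fold higher (3.07 to 6.37) and the linker histone gene Hist1h1d 2.17-fold (1.66 to 2.82). Among housekeeping mRNAs 10 of 25 were higher and 1 lower (median 0.90, percentile 99.55), with the glycolytic enzyme genes Pkm2 at 4.86-fold (4.34 to 5.45) and Ldha at 9.46-fold (6.29 to 14.5). Over Ezh2 fl/fl, Pkm2 was 2.47-fold (2.27 to 2.69) and Ldha 2.20-fold (1.71 to 2.80) higher. Ribosomal protein genes went both ways, 11 higher and 15 lower of 54, with a median of 0.28 at percentile 99.8, or 0.46 for the 50 with counts in both. Rpl22 was 3.08-fold higher (2.56 to 3.71) and Rps12 4.00-fold lower (2.75 to 6.04). Over Ezh2 fl/fl and matched on counts per kb in place of count, histone genes were at percentile 99.95, but housekeeping mRNAs (92.2) and ribosomal protein genes (39.6) were not called.

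Long neuronal genes had lower shares in Jarid2 KO cells: 15 of 19 were lower and 0 higher. The tumour suppressor gene Wwox had 7 counts against 2410 in Jarid2 WT, 84.2-fold lower (40.8 to 209.7), Immp2l was 2.59-fold lower (2.33 to 2.88), and Auts2 had a ratio of 1.98 (1.79 to 2.18). The median was -2.55, at percentile 0.05, and -1.22 for the 11 members with counts in both groups. Over Ezh2 fl/fl, 6 of 11 were lower in Jarid2 KO cells and 0 higher, with a smaller median of -1.11 at percentile 1.4. In Jarid2 WT over Ezh2 fl/fl, 10 of 21 were higher and 2 lower, with a median of 0.96. The difference between Jarid2 KO and Jarid2 WT cells followed gene span over all genes, from a median log2 ratio of 0.17 in the quintile with the shortest spans to -1.69 in the quintile with the longest. By mean share the median went from -2.08 in the lowest quintile to 0.46 in the highest. This trend cannot show a property of Jarid2 KO cells, because genes needed a minimum count over both groups. Jarid2 WT had the larger total, so genes of low share reached that minimum mostly through Jarid2 WT counts.

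Lef1, a transcription factor of the Wnt pathway (ENSMUSG00000027985, chromosome 3, 130813389 to 130927274), had 327 counts in Jarid2 KO against 17 in Jarid2 WT, 78.6-fold higher (48.3 to 137), and 253-fold higher than in Ezh2 fl/fl (146 to 479). Ntn1, encoding the guidance cue netrin (ENSMUSG00000020902, chromosome 11, 68022866 to 68214325), was 21.2-fold higher (16.997 to 26.7) than in Jarid2 WT and 15.5-fold (13.4 to 17.9) than in Ezh2 fl/fl. The glycolytic genes Gpi1 and Eno1 were 15.5-fold (13.9 to 17.4) and 20.0-fold (13.5 to 30.5) higher and Pdk1, a pyruvate dehydrogenase kinase gene, 18.7-fold (15.0 to 23.6). Uimc1, Upp1 and AC156506.2 had ratios of 23.3, 21.5 and 13.3. Camk1d (ENSMUSG00000039145, chromosome 2, 5214503 to 5635561), a calmodulin-dependent kinase gene, had 5 counts against 7927, 388-fold lower (166 to 1195), and Cdk8, a Mediator kinase gene (ENSMUSG00000029635, chromosome 5, 147042806 to 147114450), 23 against 15462, 164-fold lower (109.6 to 259.6). 2610528E23Rik was 168-fold lower (105 to 288) and the lysosomal enzyme gene Hexb 218-fold lower (85.1 to 801). Npas4, D630002G06Rik, the glutamate receptor gene Grik3 and Fmc1 were listed at 0 against 1750, 1434, 998 and 966. In Ezh2 fl/fl, Npas4 was listed at 0 too, D630002G06Rik had 3 counts and Fmc1 had 4, whereas Grik3 had 4687. Hexb and 2610528E23Rik had 96 and 340 counts in Ezh2 fl/fl against 4 and 17 in Jarid2 KO, and neither was called different there. The Cdk8 count was the highest of any gene in Jarid2 WT. Neither Cdk8 nor Camk1d was among the 10 highest genes of Ezh2 fl/fl, the last of which, Ptprg, had 9706 counts of a larger total. Their shares were thus higher in Jarid2 WT than in Ezh2 fl/fl, and part of their ratios rests on that reference.

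Among PRC2 subunits in Jarid2 KO cells, Suz12 was 2.57-fold higher (2.34 to 2.82), and Aebp2 2.64-fold (2.17 to 3.24) lower, and Ezh1 was lower too, with 7 of 10 within 2-fold. Ezh2 had a ratio of 1.47 (1.22 to 1.75), Eed 0.613 (0.412 to 0.887) and Jarid2 0.912 (0.861 to 0.967). Pluripotency genes went both ways, 5 higher and 8 lower of 33: Dnmt3b was 5.08-fold higher, Sox2 2.16-fold, and Tet2, a DNA demethylation enzyme gene, 2.40-fold lower (2.05 to 2.83). Imprinted genes did as well, 3 higher and 3 lower of 10, with Grb10 2.49-fold higher (2.14 to 2.90) and Igf2 listed at 0 against 249. Of 5 primitive endoderm markers Apoe was 14.4-fold higher (9.67 to 22.1), and Sparc, Lama1 and Col4a1 were lower. The fibroblast marker Fn1 was 2.37-fold higher (2.19 to 2.56). Eif1a had a ratio of 1.42 (1.05 to 1.90) and AC150277.2 of 1.87 (1.30 to 2.65), and no Polycomb-repressed regulator had enough counts.

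In all, 2452 of 4610 genes differed between Jarid2 KO and Jarid2 WT, where redraws gave a median of 36: 694 were higher and 1758 lower, 438 of these listed at 0. The median log2 ratio of all genes was -0.40, and median-of-ratios scaling moved it by 0.22. With Jarid2 WT thinned to the depth of Jarid2 KO, 575 genes were higher and 632 lower. Jarid2 WT counts from 2 to 9 were mostly even (70.4%), so intervals and redraws may understate their counting error. Fewer genes differed with Jarid2 WT counts halved, a later choice. In the Jarid2 KO file 42 of 1805 genes with at least 20 counts expected from their lowest share in the other deep groups were listed at 0, so a gene at 0 there was not necessarily unbound. Ezh2 fl/fl as the reference gave 504 higher and 2768 lower genes. Each genotype had 1 library, and only Jarid2 WT is tagged as given tamoxifen, so a possible treatment difference goes with genotype.

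**Figure D3:**
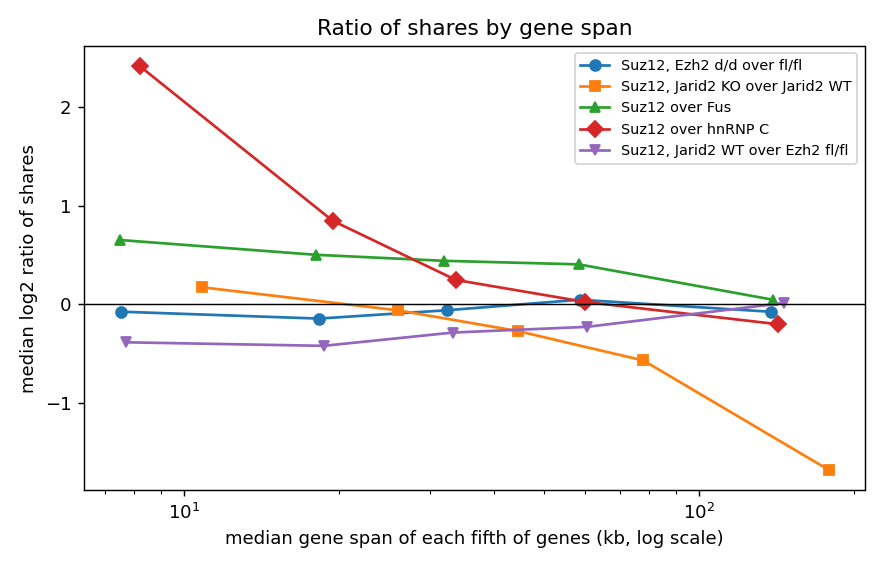
Median log2 ratio of shares (vertical axis) in each quintile of genes ordered by span, against the median span of the quintile in kb (horizontal axis, log scale), for 5 comparisons. Jarid2 KO over Jarid2 WT goes from 0.17 to -1.69, and Suz12 over hnRNP C from 2.42 to -0.20, from the shortest to the longest genes.

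Suz12 in Ezh2 fl/fl cells and Fus, an RNA-binding protein with roles in transcription and splicing, were compared to set the Suz12 profile beside that of a known RNA binder. Replication-dependent histone genes, whose mRNAs lack poly(A) tails, had higher shares with Suz12: 21 of 21 were at least 2-fold higher, and the summed ratio was 8.51 (7.57 to 9.59). Hist1h1d was 8.72-fold higher (6.20 to 12.6) and Hist1h4d 2.80-fold (2.10 to 3.80), and 14 members had counts in both, with a median of 2.43 against 3.11 for all 21. Housekeeping mRNAs (14 of 29 higher, 0 lower) and splicing factor genes (14 of 55 higher, 0 lower) had summed ratios of 1.53 (1.50 to 1.56) and 1.35 (1.34 to 1.37). All tested genes leaned the same way by totals, with a median of 0.41 and 2218 of 7493 higher. The 2 list medians were 0.98 (percentile 99.98) and 0.44 (percentile 99.8). Hsp90ab1, a chaperone gene, was 3.57-fold higher (3.23 to 3.95) and Srrm2 3.19-fold (3.03 to 3.37). Ribosomal protein genes had a lower share with Suz12, 1.27-fold (1.25 to 1.30): 18 of 71 were lower, including Rpl3 (2.08-fold, 1.89 to 2.29), 7 were higher, including Rpl4 (2.21-fold, 1.98 to 2.47), and the median of -0.34 was at percentile 0.

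Igf2 (ENSMUSG00000048583, chromosome 7, 149836673 to 149852721) had 348 counts with Suz12 and was listed at 0 with Fus, as were the histone variant gene H2afx (304 counts), Smcr7 (277), Mesdc2 (232) and Tmem5 (210). Tmed5 had 572 counts against 1 and the Wnt receptor gene Fzd7 426 against 1. Ccdc44 (ENSMUSG00000001983, chromosome 11, 105927375 to 105934926) had 1384 against 16, 77.9-fold higher (47.8 to 137), but also 21 in IgG. Tmem132d (ENSMUSG00000034310, chromosome 5, 128263861 to 128938937) had 2 against 365 with Fus, 203-fold lower (55.7 to 1679), the sorting receptor gene Sorcs2 35 against 1834, 58.2-fold lower (41.7 to 83.8), and Mcc 7 against 438, 69.5-fold lower (33.4 to 174). Lrfn2, Kcnip2, AC149086.1, Lrrc28 and Dcaf11 were listed at 0 with Suz12 against 106, 73, 73, 54 and 53 with Fus, and Kcnip2 and AC149086.1 overlap each other. Jarid2 had a 1.93-fold lower share (1.88 to 1.98) with Suz12 than with Fus, Suz12 a 3.16-fold higher one (2.89 to 3.46), and 4 of 12 PRC2 subunit genes were higher and 0 lower.

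Primitive endoderm markers had a 1.48-fold lower share (1.44 to 1.52) with Suz12 than with Fus, with 2 of 12 higher, 1 lower and a median of -0.63 at percentile 0.32. Of 4 Polycomb-repressed regulators Gata4 was 2.61-fold lower (2.26 to 3.02), Wt1 and Bmp4 were lower and 0 were higher, but with a minimum of 20 counts in place of 50 the list median turned from -2.02 to 4.22, over 10 members. Pluripotency genes (11 higher, 1 lower of 34), imprinted genes (4 and 2 of 11) and long neuronal genes (3 and 4 of 13) had medians inside the middle 95% of random lists. Sox2 was 8.59-fold higher and Dab1 lower. Fn1 was 3.22-fold higher (3.01 to 3.46), and Eif1a and AC150277.2 had ratios of 0.690 (0.607 to 0.783) and 1.72 (1.37 to 2.17). Over all genes, 2893 of 7493 differed, against 9 in redraws, 2218 higher with Suz12 (83 listed at 0 with Fus) and 675 lower. TMM scaling moved the median by -0.41 and median-of-ratios scaling by -0.39, which gave 1487 higher and 1248 lower, and 1509 higher and 1222 lower.

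Compared with hnRNP C, a nuclear protein that binds uridine-rich introns, Suz12 had higher shares in genes of short span, with a median log2 ratio of 2.42 in the quintile with the shortest spans and -0.20 in that with the longest. Fus over hnRNP C had 1.64 in the shortest and -0.16 in the longest, so higher shares in short genes were not particular to Suz12. By mean share the median was 2.34 in the lowest quintile and -0.27 in the highest. This trend cannot show a property of Suz12, since genes of low share reached the minimum count mostly through the larger Suz12 total. Of 66 ribosomal protein genes 53 were higher and 4 lower, with a summed ratio of 2.71 (2.59 to 2.84), and the 38 members with counts in both had a median of 1.75. Rpl22 was 11.6-fold higher (7.96 to 17.8), Rpl3 (ENSMUSG00000060036, chromosome 15, 79908226 to 79913781) had 664 counts and was listed at 0 with hnRNP C, and Rps24 was 2.11-fold lower (1.91 to 2.32). All 17 measured histone genes were higher, 15 of them listed at 0 with hnRNP C, with a summed ratio of 52.3 (32.6 to 89.8). Housekeeping mRNAs were higher for 20 of 29 and lower for 2 (ratio 1.97, 1.90 to 2.04), with the translation factor gene Eif4a1 9.62-fold higher (7.63 to 12.3). Splicing factor genes went both ways, 12 higher and 6 lower of 55, with a summed ratio of 0.764 (0.755 to 0.773) but a median of 0.11, at percentile 99.3: Ddx17 was 3.20-fold lower (3.08 to 3.33) and Srrm2 3.67-fold higher (3.35 to 4.03).

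Flna, encoding the actin crosslinker filamin (ENSMUSG00000031328, chromosome X, 71468800 to 71495159), had 1695 counts with Suz12 and was listed at 0 with hnRNP C. So were Ccdc44 (1384), ORF19 (910), the chaperone gene Hsp90aa1 (731), Acot1 (577), the endocytic receptor gene Cubn (570) and Sfrs16 (560). In the hnRNP C file 91 of 3180 genes with at least 20 counts expected, by the same lowest share, were listed at 0. The lincRNA gene 4933436C20Rik (ENSMUSG00000031736, chromosome 8, 94849937 to 94880019) had 4 counts with Suz12 and 71 with hnRNP C, 58.7-fold lower (21.9 to 221), and Rnf166, AC125279.1, 2410091C18Rik, Tsen15, Mns1, Cbwd1 and Alkbh3 were from 12.1- to 31.1-fold lower. Primitive endoderm markers had a 2.53-fold higher share (2.39 to 2.68), 9 of 12 higher and 0 lower, with Sparc 6.35-fold higher (4.96 to 8.26). Pluripotency genes were higher for 13 of 33 and lower for 1 (median 0.58, percentile 96.5), with Pou5f1, encoding Oct4, 6.30-fold higher. Imprinted genes (5 of 10 higher, 1 lower), long neuronal genes (1 of 12 higher, 3 lower) and PRC2 subunits (2 of 12 higher, 2 lower) had medians inside the middle 95%. Suz12 had a 2.66-fold lower share (2.496 to 2.83) with Suz12 than with hnRNP C, Jarid2 1.49-fold lower (1.44 to 1.55), Ezh2 1.37-fold (1.25 to 1.501) lower and Eed a ratio of 1.27 (1.06 to 1.52). Gata4, Gata6, Fn1 and Eif1a were within 2-fold, and AC150277.2 was 9.63-fold higher (4.60 to 24.2).

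Between Suz12 and hnRNP C 3467 of 6946 genes differed (28 in redraws), 2647 higher, of which 726 were listed at 0 with hnRNP C, and 820 lower. Fus and hnRNP C, set against each other as a scale, differed at 3646 of 6101 genes, with 2030 higher and 1616 lower by totals, and 2358 and 1207 by TMM, which moved the median by 0.34. Between them ribosomal protein genes were higher with Fus for 54 of 64 and lower for 3 (ratio 3.45, 3.29 to 3.61), and primitive endoderm markers for 10 of 11 and 0 (3.74, 3.54 to 3.96). Splicing factor genes were higher for 11 and lower for 21 of 55, 1.77-fold lower in sum (1.75 to 1.79) but with a median of -0.44 at percentile 24.2, inside the middle 95% of random lists. Matr3 was 5.87-fold lower (5.54 to 6.22).

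**Figure D4:**
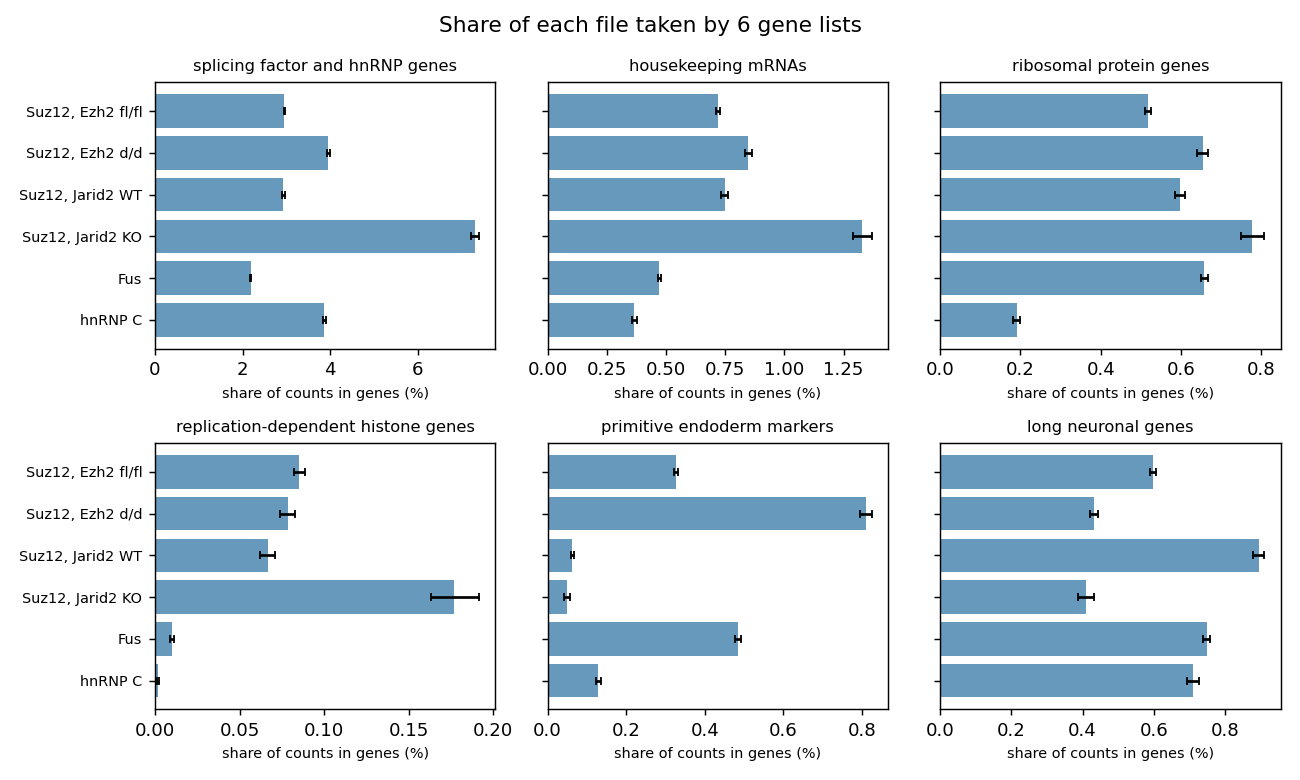
Share of all counts in genes (%, bars starting at 0) taken by 6 gene lists in 6 groups, with exact binomial 95% intervals. Splicing factor and hnRNP genes reach 7.31% in Suz12 of Jarid2 KO cells, primitive endoderm markers 0.810% in Ezh2 d/d, and ribosomal protein genes are lowest for hnRNP C.

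Eed was precipitated to ask whether a further PRC2 subunit contacts the same RNAs as Suz12. No untagged control of the Eed line was among the samples, so the line goes with the protein. Pluripotency genes took 2.13% of Eed counts (1.78 to 2.52), 0.962% of Suz12 counts in Ezh2 fl/fl and 0.730% of IgG counts (0.468 to 1.08). Of 32 members 6 were higher, 2 lower and 24 neither, and the median was inside the middle 95% of random lists (percentile 90). Tcfcp2l1, a transcription factor of naive pluripotency (ENSMUSG00000026380, chromosome 1, 120524527 to 120579448), had 48 of the 131 Eed counts of the list, a share 32.1-fold higher (23.5 to 43.0) than with Suz12, and the syndecan gene Sdc4 had 36 (29.4-fold, 20.4 to 41.1). Without Tcfcp2l1 the summed pluripotency ratio was 1.44 (1.15 to 1.78), against 2.21 (1.85 to 2.63) with it. Housekeeping mRNAs took 1.92% with Eed (1.59 to 2.29), 0.721% with Suz12 and 1.52% with IgG (1.13 to 2.00), so the Eed and IgG shares overlapped. Splicing factor genes likewise took 4.88% with Eed and 4.44% with IgG, against 2.95% with Suz12. Primitive endoderm markers took 0.0975% with Eed (0.0358 to 0.212), a lower share than with Suz12.

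Efna5, Tmem181a, C330007P06Rik, Trh, Mudeng and Rpl29 had 5 to 10 Eed counts and higher shares than with Suz12. Fgfr2, Ctbp2, Arl15, Smyd3, 4933407C03Rik, the Notch effector gene Rbpj, the perlecan gene Hspg2 and Phf17 were listed at 0 with Eed against 6017 to 19752 with Suz12. Ribosomal protein genes had shares of 0.602% with Eed and 0.518% with Suz12 (ratio 1.16, 0.818 to 1.60), PRC2 subunit genes a ratio of 1.38 (1.03 to 1.82), with Jarid2 at 1.38 (0.887 to 2.06), long neuronal genes 0.653 (0.418 to 0.971), imprinted genes 0.479 (0.176 to 1.04), histone genes 0.761 (0.207 to 1.95) and Polycomb-repressed regulators 3.82 (1.04 to 9.83) on 4 Eed counts. Fn1 was 3.09-fold higher (1.88 to 4.77) by totals but had a ratio of 0.745 (0.455 to 1.15) by TMM, and Eif1a and AC150277.2 had 0 Eed counts. By totals, 639 of 6565 genes differed (76 in redraws), 513 higher and 126 lower. TMM scaling moved the median by -2.05, giving 96 higher and 1357 lower, and median-of-ratios scaling by -1.76, giving 130 and 1056, so the direction of the split depends on the scaling. By TMM the summed ratios were 0.535 (0.447 to 0.635) for pluripotency genes, 0.643 (0.532 to 0.770) for housekeeping mRNAs and 0.399 (0.355 to 0.447) for splicing factor genes. They were 0.334 (0.249 to 0.440) for PRC2 subunit genes, 0.281 (0.197 to 0.387) for ribosomal protein genes and 0.922 (0.250 to 2.37) for Polycomb-repressed regulators. Tcfcp2l1 and Sdc4 were still 7.76-fold (5.67 to 10.4) and 7.10-fold (4.93 to 9.93) higher. The Spearman correlation of Eed with Suz12 was 0.334, against 0.615 from thinning alone.

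Jarid2 WT and Ezh2 fl/fl cells, both with unmodified PRC2, were compared as a measure of how far Suz12 libraries of different lines differ, though only Jarid2 WT is tagged as given tamoxifen. Primitive endoderm markers had a 5.17-fold lower share (4.83 to 5.55) in Jarid2 WT cells, 10 of 11 lower and 0 higher, with Lama1 9.00-fold lower (7.79 to 10.5), Lamb1-1 10.5-fold (7.89 to 14.3) and Cubn 116-fold (32.0 to 960.2) lower. Pluripotency genes had a median of 0.11, at percentile 98.7, with Klf2 6.03-fold higher, Dnmt3b and Lin28 lower, and 30 of 35 within 2-fold. Npas4 (1750 counts) was listed at 0 in Ezh2 fl/fl, and D630002G06Rik had 1434 counts against 3. Fmc1 had 966 counts against 4, 2610528E23Rik 84.2-fold more of the counts (75.6 to 94.0), and AC091681.1, Best3, AC141209.3 and Cdh13 were listed at 0 in fl/fl. Eif2s3y, 2610002J02Rik, Fibcd1, the glycolytic gene Pgk1 and Dnm1 were listed at 0 in Jarid2 WT against 276, 179, 158, 143 and 128, and Gata4 and Trio were 54.7-fold (15.0 to 454) and 28.4-fold (14.9 to 62.5) lower. Splicing factor genes had a ratio of 0.992 (0.981 to 1.00). By totals 581 genes were higher and 1559 lower, where the excess of even counts in Jarid2 WT may understate counting error. Median-of-ratios scaling moved the median by 0.26 and gave 859 and 1123.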

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

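No paired analysis was possible because the deposited tables pool the libraries of a group, although the labels number libraries 1 to 3 in both Ezh2 fl/fl and Ezh2 d/d. For the same reason a replicate block, edgeR quasi-likelihood and DESeq2 tests, leaving out each replicate, and a comparison at the lower UV dose alone were not run. Pseudocount and filter alternatives for normalized values did not apply, since the tables hold counts. No mitochondrial gene is in the tables, so only the 20 genes with the highest counts were left out. Of the counts of different genes, 59 of 82 alternatives stayed the same and 23 moved. This compares only the total number of different genes, not how many were higher or lower. That split could still change greatly, as for Suz12 over Fus by TMM scaling and Jarid2 WT over Ezh2 fl/fl by median-of-ratios scaling. Of list results 222 of 227 and of named-gene bounds 319 of 320 stayed the same. These tallies are weak support. TMM scaling shifts all genes of a comparison alike, so it can hardly move a list percentile. The named genes were picked for bounds far from 1, so most alternatives could hardly change their calls.

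With at least 200 counts in place of 50, fewer genes were tested and fewer differed: 999 for Ezh2 d/d over fl/fl, 886 for Jarid2 KO over WT, 1414 for Suz12 over Fus, 1575 over hnRNP C, 1892 for Fus over hnRNP C and 834 for Jarid2 WT over Ezh2 fl/fl. With no minimum count, more were tested, and 3741, 4190, 5057, 5257, 5705 and 4541 differed. With a 1.5-fold ratio, 3696 genes differed for Ezh2 d/d, 4442 for Suz12 over Fus and 3475 for Jarid2 WT over fl/fl, a looser threshold.

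Thinning the deeper table left fewer counts and 1207 genes for Jarid2 KO over WT (47.6% higher, against 28.3%), 2161 for Suz12 over hnRNP C and 3 of 5 for Eed. With all Suz12 tables thinned to the Jarid2 KO total, chosen after seeing the data, 653 genes differed for Ezh2 d/d, 1216 for Jarid2 KO over WT and 517 for Jarid2 WT over fl/fl. Other choices made after seeing the data were counts above 0 in both tables, overlap on either strand, and for Jarid2 KO halved Jarid2 WT counts (1703 genes) and Ezh2 fl/fl as the reference (3272).

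Scaling moved the Eed count from 639 to 1453 by TMM and 1186 by median-of-ratios factors. Both scalings rest on genes with counts in both tables, which only 1244 of 6565 tested genes had. The cause of the shift was not tested. Summed Eed ratios under these scalings, computed after seeing that shift, turned from higher to lower for pluripotency genes (0.535 by TMM, 0.652 by median-of-ratios factors), housekeeping mRNAs (0.643, 0.784), splicing factor genes (0.399, 0.487) and PRC2 subunits (0.334, 0.408). Of all 29 such alternatives 9 stayed the same, 8 reversed, 6 were weaker and 6 stronger, with pluripotency genes without Tcfcp2l1, also a later choice, at 1.44. With thinned tables, Mudeng in Eed no longer cleared the threshold (bound 0.916).

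For yield, genes counted after thinning to the smallest control total gave ratios of 1.98 over Suz12 KO (1209 against 612 genes) and 1.42 over IgG (1209 against 849). These compare spread over genes, not amount. Without the 20 highest genes the ratio to IgG was 168.

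With at least 200 counts the correlation of profiles with Suz12 in Ezh2 fl/fl was 0.790 for Ezh2 d/d, 0.789 for Fus, 0.704 for hnRNP C and 0.2996 for Eed, and that of Jarid2 KO with WT was 0.524. With thinned tables that of Eed was 0.245. The cause was not tested.

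Among gene lists, Polycomb-repressed regulators in Suz12 over Fus reversed with at least 20 counts, from -2.02 over 4 members to 4.22 over 10; the cause was not tested. In Suz12 over hnRNP C the pluripotency median was 0.78 with at least 20 counts and 0.53 with counts in both tables, past the percentile threshold that 0.58 missed. Primitive endoderm markers there had medians of 1.32 with at least 20 counts and 1.25 without overlapping genes, just short of the threshold that 1.29 passed. Their causes were not tested.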

Other observations

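Primitive endoderm markers had shares that differed among cell lines as well as among proteins. They took 0.810% of Suz12 counts in Ezh2 d/d, 0.327% in Ezh2 fl/fl, 0.0631% in Jarid2 WT and 0.0482% in Jarid2 KO cells. Against Ezh2 fl/fl, 10 of 11 markers were lower in Jarid2 KO cells, among them the laminin gene Lama1 (7 counts against 4247), and the lipid carrier gene Apoe was 2.72-fold higher.

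LincRNA genes took 0.743% of Suz12 counts in Jarid2 WT, 0.578% in Jarid2 KO, 0.422% in Ezh2 fl/fl and 0.393% in Ezh2 d/d cells, against 0.424% with Fus and 0.516% with hnRNP C. Between Fus and hnRNP C, Suz12 RNA had an 8.40-fold lower share (7.66 to 9.21) with Fus, and Cntfr, encoding a neurotrophic factor receptor, had 1282 counts with Fus and was listed at 0 with hnRNP C.

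Of the tests below, those of gene span, of the spread of primitive endoderm ratios, of the splicing factor reference, of 1 factor moving all genes, and of the glycolysis genes measured over both references were chosen after the result was seen.

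Some genes, such as Npas4 and Hexb, were counted mainly in the Suz12 Jarid2 WT table. Of 9691 genes listed at 0 everywhere else, 1048 had counts there, 0.535% of its counts and 8.48 times the next table's share. Over all 9691 genes, of which 8643 had 0 counts in this table too, count rose with gene span (Spearman 0.361). A background spread along the genome may explain part of them. The correlation was not computed for other tables, so it cannot decide this. Gphn, Lars2 and Hexb were set down before their values were seen as genes that draw reads of repeated or ribosomal RNA. They had a median ratio of 47.2 over Ezh2 fl/fl (Gphn 16.8, Lars2 47.2, Hexb 91.3), so reads of such sequence may explain others. Hexb is itself an example of the pattern, which leaves Gphn and Lars2 as the separate check. All tested genes had a median log2 ratio of -0.25 over Ezh2 fl/fl. This cannot decide on a single factor moving all genes alike, because shares of a table's total largely cancel it. Which source each gene has stays open.

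Primitive endoderm markers were higher in Ezh2 d/d as a group. A larger share of primitive endoderm-like cells in the tamoxifen cultures could give this. The SD of the 12 log2 ratios was 0.511 times that of count-matched genes. Such evenness cannot decide, since a joint change in transcription or in Suz12 binding could give it too. The median log2 ratio was -0.0659 for all tested genes and 1.37 for the markers. This cannot decide on a single factor moving all genes alike, since shares of a table's total largely cancel it. Without Lama1, the marker with the most counts, the summed ratio was 2.83 (2.74 to 2.92). Lama1 had a lower ratio than the list, so leaving it out had to raise the sum and cannot decide on a dominant marker. A dominant single marker was argued against by the calls, with 9 of 12 markers at least 2-fold higher. The 3 measured fibroblast markers had a median at percentile 99.92 as well, so the call was not limited to primitive endoderm. An effect of Ezh2 loss on transcription or on Suz12 binding of these RNAs is untested, because no measure of RNA amount is in the tables and genotype goes with library.

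Splicing factor genes were higher in Suz12 of Jarid2 KO cells. The choice of reference was argued against, with a ratio of 2.48 against Ezh2 fl/fl. A low depth favouring genes with dense counts was argued against too, since the list was at percentile 100 among lists matched on counts per kb and histone genes at 99.95, while housekeeping mRNAs (92.2) and ribosomal protein genes (39.6) were not called. Loss of Jarid2 could still underlie the higher splicing factor shares, but this is untested with 1 library per genotype and differing tamoxifen tags, and IgG had a share of 4.44%.

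A hypothesis from Pdk1, Gpi1 and Eno1 was that glycolysis and hypoxia-response genes are higher as a group in Jarid2 KO cells. Over Jarid2 WT the list was at percentile 99.8 (6 higher and 3 lower of 13), but over Ezh2 fl/fl at percentile 72.2 (8 higher and 6 lower of 24). Pkm2 and Ldha, among the higher members over Jarid2 WT, are also in the housekeeping list, so that percentile does not rest on separate genes alone. The 13 genes measured over both were at percentile 74.4 over Ezh2 fl/fl (5 higher and 3 lower). The result depends on the reference, so low shares in Jarid2 WT may explain it.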
